A study of Mus musculus with 28 samples.

How the data were processed

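Polyadenylated RNA of liver and kidney from male db/db mice was sequenced by the authors as stranded libraries read in pairs, per the labels' protocols. The submitters' processing notes name CASAVA, FastQC, Trimmomatic 0.36, STAR 2.7.9a, featureCounts 2.0.1 and StringTie 2.1.4, without the role or order of each, and the genome build GRCm39. The strand setting of the counting and any scaling between libraries are not given in the sources used here.

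The values of both tables are FPKM as deposited by the authors. The liver table holds 66878 transcripts, whose FPKM were summed here to 22116 genes, 4659 of them at 0 in every library. The kidney table holds 23650 genes or loci, of which 21797 carried a gene name, 3895 of them at 0 in every library. Transcripts or loci without a gene name, 470 in liver and 1853 in kidney, were left out of the tests of genes and lists. They held 0.17 to 0.27% of the summed FPKM of a liver library and 3.13 to 11.53% of a kidney library. The tables were made separately for the 2 tissues, so tests are within a tissue. The reference annotation at hand was of another mouse build, so no coordinates are given, and it was used for transcript lengths (65246 of 66408 liver transcript identifiers matched) and for which genes overlap. Of the 179 named genes found in it, 31 overlap a gene on the opposite strand and 8 a gene on the same strand, and their values, like those of near-identical copies, are uncertain.

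Low values were searched for the step that 1 fragment would make, given the transcript length: 17 to 24.4% of low liver values and 11.7 to 28.1% of low kidney values lay within 0.05 of a whole multiple of the best step, against 6.8 to 9.1% and 6 to 10.7% with a step that no fragment would make, too few to recover counts. Precision is given by the spread between libraries.

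Groups and replicate numbers came from the sample labels, which do not tie libraries to separate animals, so p-values measure the spread between these samples, which may be technical. No 2 libraries were identical, and the highest correlation of a pair was 0.9926 in liver and 0.9882 in kidney.

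Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 liver or 4 kidney libraries were tested. limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend) in R 4.3.3 was fitted to the 4 groups of a tissue at once, with no block, and p-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The comparisons were each treatment against control, combined treatment against each single treatment, and the interaction. Differences between tissues were tested from the 2 limma estimates and standard errors with Satterthwaite degrees of freedom, which treats the estimates as independent; whether liver and kidney libraries came from the same mice is not given in the sources used here. The figure was drawn with Python 3.11.15 and matplotlib 3.10.9.

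In advance 50 gene lists for pathways and cell types were fixed, and those with at least 5 tested members were used, 30 in liver and 39 in kidney. They were tested with camera at a preset correlation of 0.01 between genes and at an estimated one, and with fry, adjusted over the lists of a comparison. Overlaps between treatments were set beside 100 simulations of unchanged groups with the same controls.

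Genes were named by a fixed rule. For each treatment against control it took the 10 largest changes in each direction among genes that passed and whose groups did not overlap, and for the other comparisons 5. A direction with fewer than 5 was filled to 5 by the smallest p without overlap (unchecked for interactions). Up to 4 members with the smallest p of each called list were added, with Glp1r, Lepr and Insr. Between tissues it took 5 genes that passed in the same direction in both and 5 with the smallest adjusted p of the difference. Predicted genes, pseudogenes, genes without a symbol and immunoglobulin or T cell receptor segments were counted but not named, and a few genes that the rule picks are not reported here. Transcripts of other cell types given as levels per library were singled out after their values were seen.

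The gene test was tried on data simulated on the semaglutide comparison with 200 changed genes. In liver it recovered 71.6, 95.5 and 100% of genes changed by 1, 2 and 3 (log2) with 11 false calls. In kidney it recovered 77.6, 97 and 100% with 7. It made 0 calls with no change. Such rates need not hold here, as libraries diverged. The list test recovered the 1 list moved, and 0 others, in data simulated without correlation between genes. Alternatives were a pseudocount of 0.1, no filter, median-ratio scaling, the replicate number as a block, only the groups compared in the fit, liver transcripts one by one, an estimated correlation, and each library left out. Leaving out the divergent libraries (liver control 3 and semaglutide 2, kidney control 1), removing mitochondrial transcripts and scaling the other splits were added after the data had been seen.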

Results

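Messenger RNA was profiled in liver and kidney of male db/db mice, which carry a defective leptin receptor and become obese and diabetic. Intervention began at 8 weeks of age and lasted 8 weeks. The 4 groups were sedentary controls, high-intensity interval training (HIIT) on a treadmill, semaglutide (a long-acting agonist of the GLP-1 receptor), and both together (combined). The labels give the semaglutide dose as 0.05 mg/kg in one place and as 30 nmol/kg in another, different amounts, and which was used is open. Each group had 3 liver libraries (12 in all) and 4 kidney libraries (16 in all). Values are FPKM (mapped fragments scaled to transcript length and to the library's total) and hold no read counts, so the depth of each library is unknown. Summed FPKM ran from 518967 to 552993 per liver library and from 495273 to 662489 per kidney library.

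Log2 changes below are on the log2(FPKM + 1) scale, with their standard error after ±, and understate the change of weakly expressed genes. limma tested 10348 genes in liver and 11551 in kidney, with Benjamini-Hochberg adjusted p-values. Between 2 groups, every gene named as passed had no overlap, so its direction held in each library. Chance gives this to 10% of genes with 3 libraries against 3. Gene lists fixed in advance, 30 in liver and 39 in kidney, were compared with all other genes by camera at a preset correlation of 0.01 within a list. With a correlation estimated from the data, camera called 0 lists throughout, and 0 to 4 per comparison had unadjusted p under 0.05. The adjusted p with this estimate is given beside each call. Genes counted as unadjusted had an unadjusted p under 0.05, as a 0.05 share would by chance. Kidney counts of 132, 345, 384 and 456 of 11551 are below that share.

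Liver library semaglutide 2 held the skeletal muscle transcripts Acta1 at 3900 FPKM and Mb at 2730 FPKM, against at most 0.138 and 0.0448 in every other liver library. It also held the highest liver level of the adipocyte transcripts Adipoq (137 FPKM against at most 0.0688) and Fabp4 (1150 against at most 17), of the plasma cell transcript Jchain (310 against at most 1.1) and of the haemoglobin gene Hbb-bs (1080 against at most 338). Liver library control 3 had the highest median level of the 12 for the acute phase, macrophage and neutrophil lists, with Saa1 at 26100 FPKM, while Lyz2, a macrophage transcript, was highest in semaglutide 2 (223 FPKM, and 198 in control 3). Its median correlation with the other liver libraries was 0.939 and that of semaglutide 2 was 0.9, against 0.976 to 0.983 for the rest. In kidney, library control 1 stood apart with a median correlation of 0.91. It held Lyz2 at 2710 FPKM against at most 51 elsewhere, Cd74 at 1950 against at most 204, Jchain at 1260 against at most 3.41 and Col1a1 at 77.8 against at most 10.9. Kidney library semaglutide 4 had the highest Adipoq, 37.2 FPKM against at most 5.44, and Fabp4, 295 against at most 81.8.

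Transcripts of the GLP-1 receptor gene Glp1r were scarce, with group means of 0.008 to 0.047 FPKM in liver and 0.259 to 0.394 FPKM in kidney, as were those of Lepr, which encodes the leptin receptor (0.148 to 0.42 and 0.346 to 0.794), and neither was tested. Insr, the insulin receptor gene, averaged 10 to 11 FPKM in the 4 liver groups and, in kidney, 8.84 ± 0.933 FPKM in controls, 13.2 ± 3.28 with HIIT, 11.1 ± 4.56 with semaglutide and 15.2 ± 3.83 with both, none of which passed.

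Mitochondrially encoded transcripts made up 17.69 ± 3.03% of the summed FPKM (SD, n = 3) in control liver, 19.71 ± 1.61% with HIIT, 23.77 ± 1.44% with semaglutide and 22.29 ± 3.18% with both. In kidney the shares were 32.17 ± 7.87% (SD, n = 4) in controls, 44.48 ± 13.86% with HIIT, 39.76 ± 6.65% with semaglutide and 38.58 ± 7.19% with both. By exact two-sided permutation tests the 6 differences from control had p of 0.1 to 0.5, and 0.386 to 0.5 adjusted over the 6. The liver tests, with 3 against 3, cannot go below 0.1.

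HIIT against control in the liver asked what training alone did. No gene passed, but several transcripts had much lower levels in the trained livers. Saa1, an acute phase protein gene, averaged 721 ± 815 FPKM (SD, n = 3) against 14720 ± 11800 in controls (log2 change -4.42 ± 0.93), and Saa2, a close copy with which reads may be shared, had -4.97 ± 1.05. Gadd45g, a stress-inducible growth regulator, had -2.52 ± 0.47, the phosphatase regulator Ppp1r10 -1.05 ± 0.23 and the guanylate-binding protein gene Gbp11 -0.78 ± 0.16. Higher levels were seen for Map2k6, a kinase upstream of p38 (1.04 ± 0.20), Ssc4d (1.04 ± 0.23), Fech, the last enzyme of haem synthesis (1.00 ± 0.22), Clec14a (0.74 ± 0.16) and Zfyve1 (0.52 ± 0.11). These 10 genes had the smallest p among genes whose groups did not overlap, each with limma adjusted p = 0.676. limma called 0 of the 10348 genes, with 747 unadjusted; without library control 1 it called 106, and 6 when transcripts were tested one by one.

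Among the lists, camera called 15 with HIIT in liver, 8 higher and 7 lower. The acute phase list had lower means for 18 of its 19 measured members, with a median of -1.91, with Orm2 (-2.91 ± 0.67) and Lcn2 (-3.92 ± 1.04), and was called lower (adjusted p = 3.11e-23, and adjusted p = 0.566 with an estimated correlation). Its median level was 8.02, 10.39 and 11.42 (log2) in liver libraries control 1, 2 and 3, and control 3 also held the highest medians of the macrophage and neutrophil lists, 3.73 and 3.53. Complement genes were called lower with all 14 members below control (median -0.65), among them C3 (-0.86 ± 0.25), at adjusted p = 7.6e-09 and adjusted p = 0.644 with an estimated correlation. Interferon response genes (17 of 23 below control, median -0.2, with Zbp1 at -2.02 ± 0.58) and immediate early genes (12 of 14, median -0.71, with Nr4a1 at -1.15 ± 0.41 and Dusp1 at -0.81 ± 0.33) were called lower at adjusted p = 5.97e-05 and 7.67e-06, both with adjusted p = 0.718 with an estimated correlation. Xenobiotic metabolism genes were called higher, 15 of 19 above control with a median of 0.58, among them Cyp2c29 (1.33 ± 0.55) and Nr1i3, the xenobiotic sensor CAR (0.92 ± 0.30), at adjusted p = 0.00353. Erythroid genes were called higher, 5 of 5 with a median of 1.41, at adjusted p = 0.000539, led by the near-identical pairs Hba-a1 (1.42 ± 0.43) and Hba-a2 and Hbb-bs (1.53 ± 0.50) and Hbb-bt. For both lists adjusted p = 0.718 with an estimated correlation. Of the 94 members of these 6 lists limma called 0 over all genes 25 adjusted over the list alone and 34 unadjusted. Without control 3 the medians of xenobiotic, complement, interferon and immediate early genes were 0.36, -0.18, -0.08 and -0.43; complement was -1.11 without control 1 and interferon -0.33 without control 2.

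The other 9 calls with HIIT in liver each ended without some library. Genes of fatty acid synthesis (Dgat2, 0.46 ± 0.15), fatty acid oxidation (FAO; Acadm, 0.35 ± 0.15), cholesterol synthesis, bile acids (Slco1b2, 0.67 ± 0.26), oxidative phosphorylation (OXPHOS) and the circadian clock (Dbp, 0.90 ± 0.31) were called higher, and macrophage markers, MHC class II and cell cycle genes lower. Their adjusted p ran from 0.000539 to 0.0464, and adjusted p = 0.718 to 0.866 with an estimated correlation. limma called 0 of their 166 members over all genes and 0 adjusted over the list alone, with 12 unadjusted. Omitting control 3 ended 8 of the 9 calls (adjusted p 0.0536 to 0.775) and turned cholesterol synthesis and MHC class II; control 1 or control 2 ended 1 each (0.0692, 0.179), HIIT 1 or HIIT 2 ended 3 each (0.0644 to 0.255, 0.143 to 0.25) and HIIT 3 ended 1 (0.0541). Without control 3 the calls numbered 9 in all, and median-ratio scaling ended the call of MHC class II (adjusted p = 0.152).

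Semaglutide against control in the liver asked what the drug alone did. Of the genes that passed, Cidec, a lipid droplet fusion protein, had the largest rise, from 2.64 ± 1.07 FPKM in controls to 84.5 ± 95.3 (SD, n = 3; log2 change 4.00 ± 0.77). It was 32.0, 195 and 27.1 FPKM in semaglutide 1, 2 and 3, and semaglutide 2 held adipocyte transcripts (Adipoq, 137 FPKM); without that library the change was 3.1 with limma adjusted p = 0.0625, and leaving out any 1 of the 6 libraries ended the call (adjusted p 0.0532 to 0.146). Fitm2, a protein of droplet formation, rose (1.17 ± 0.18), as did Crat, carnitine acetyltransferase (1.69 ± 0.27), Acot2, a mitochondrial acyl-CoA thioesterase (1.74 ± 0.33), Slc25a20, the acylcarnitine carrier (0.64 ± 0.10), Acadm (0.82 ± 0.15), the hormone gene Fgf21 (1.65 ± 0.32) and Pex11a, a peroxisome division factor (1.34 ± 0.22). Bnip3, a mitophagy receptor (1.29 ± 0.15), Wee1, a cell cycle kinase (1.27 ± 0.21), Dapk2 (1.20 ± 0.23) and Tomm40l (1.63 ± 0.28) also rose, as did the clock genes Per2 (1.03 ± 0.14) and Cry1 (0.63 ± 0.12). Tomm40l and Nr1i3 overlap on opposite strands and the strand setting of the counting is not given, so their values are uncertain.

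Genes that fell with semaglutide in liver included Hsd17b6, a steroid dehydrogenase (-1.97 ± 0.34), Sds, serine dehydratase (-1.67 ± 0.29), Slc7a2, a cationic amino acid transporter (-1.42 ± 0.21), Acmsd, an enzyme of tryptophan breakdown (-1.37 ± 0.26), and the keratin gene Krt18 (-1.70 ± 0.24). Insc fell by 1.48 (SE 0.20) and Ptgds, prostaglandin D2 synthase, by 1.42 (SE 0.27). Also lower were Apol9a (-1.88 ± 0.30) and Apol9b (-1.91 ± 0.26), near-identical copies, the complement gene C8b (-1.36 ± 0.24), Abcg5, a sterol exporter (-1.34 ± 0.25), Nr0b2, a bile acid responsive repressor (-1.17 ± 0.22), and the RNA sensors Dhx58 (-0.73 ± 0.11) and Ifih1 (-0.66 ± 0.11). The limma adjusted p of these genes and those that rose ran from 0.0213 to 0.0469.

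limma called 74 liver genes with semaglutide, 26 higher and 48 lower, 36 of them changed at least 2-fold, with 1579 unadjusted. Without the divergent libraries semaglutide 2 and control 3 it called 58, 31 of the 74 among them, and all 74 kept their sign. The count was 252 without control 1, 0 without control 2, 15 without control 3, 43 without semaglutide 1 and 1 without semaglutide 3. After scaling 16 were higher and 47 lower, 25.4% higher against 35.1% as deposited. With replicate number as a block 10 were called, without a filter 23, as transcripts one by one 7, and with only the groups compared 0.

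Camera called 15 lists with semaglutide in liver, 8 higher and 7 lower. Lipid droplet and fatty acid uptake genes were called higher, with 16 of 17 members above control, a median of 1.11, and G0s2 at 1.65 ± 0.37 and Mogat1 at 1.07 ± 0.25 below the threshold. FAO and ketogenesis genes were called higher with 24 of 27 above control (median 0.64). These 2 lists had adjusted p = 1.03e-06 and 4.61e-07, and for both adjusted p = 0.331 with an estimated correlation. The first holds Fabp4 and other adipocyte transcripts that library semaglutide 2 held in excess, and its median was 0.65 without that library and 0.44 without both divergent libraries. Acute phase genes (19 of 19 below control, median -1.75, with Orm2 at -2.56 ± 0.67), complement genes (14 of 14, median -0.65, with C6 at -1.81 ± 0.50) and interferon genes (20 of 23, median -0.55, with Isg15 at -0.97 ± 0.23) were called lower at adjusted p = 1.2e-13, 6.41e-09 and 6.53e-10, each with adjusted p = 0.331 with an estimated correlation. OXPHOS genes (30 of 30, median 0.44, with Ndufb8 at 0.67 ± 0.21) were called higher at adjusted p = 6.12e-07 (adjusted p = 0.664 with an estimated correlation); the median was 0.19 without semaglutide 2, which held muscle transcripts (Mb, 2730 FPKM), 0.29 without control 3, and 0.04 without both, which ended the call (adjusted p = 0.0926). So were heat shock genes (10 of 11, median 0.69, with Hspa8 at 1.07 ± 0.23) and erythroid genes (4 of 5, median 2.3), at adjusted p = 0.00152 and 0.00401, both with adjusted p = 0.443 with an estimated correlation. The erythroid list's median level was 4.6 to 5.45 (log2) in the 3 liver controls and 8.8 in semaglutide 2, without which the heat shock median was 0.26. Without control 3 acute phase, complement and interferon medians were -1.05, -0.35 and -0.3, and complement was -1.01 without control 1. These 8 lists held 146 members, of which 8 passed over all genes, 60 adjusted over the list alone and 81 unadjusted.

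Another 7 lists were called with semaglutide in liver. Endothelial markers (Lyve1, 1.40 ± 0.38), mitochondrially encoded mRNAs (mt-Co1, 0.60 ± 0.27) and clock genes were higher, and cholesterol synthesis, bile acid, male-biased (C8b) and hepatocyte secreted protein genes (Ambp, -1.19 ± 0.34) lower. Their adjusted p ran from 4.32e-05 to 0.0496, and adjusted p = 0.443 to 0.691 with an estimated correlation. Of their 114 members 6 passed over all genes, 15 adjusted over the list alone and 30 unadjusted. Omitting semaglutide 2 ended 5 of these calls (adjusted p 0.0593 to 0.775) and turned bile acids and secreted proteins, control 1 ended 3 (0.0623 to 0.739) and turned cholesterol synthesis, semaglutide 3 ended 2 (0.0508, 0.0767), and control 2 and semaglutide 1 ended 1 each (0.0563, 0.088). Scaling ended the call of secreted proteins (adjusted p = 0.0959).

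Combined treatment against control in the liver asked what training and drug did together. Of the genes that passed, Nr1i3 had the largest rise, from 75.7 ± 32.9 to 304 ± 23 FPKM (SD, n = 3; log2 change 2.07 ± 0.30), with its neighbour Tomm40l (1.90 ± 0.28). The Nr1i3 call ended without control 2, control 3 or any combined library (limma adjusted p 0.0628 to 0.152), without a filter (0.0673) and with the block (0.0611). Wee1 (1.59 ± 0.21), Per3 (1.47 ± 0.21), Per2 (0.91 ± 0.14), Pex11a (1.47 ± 0.22) and Bnip3 (1.14 ± 0.15) rose, as did Defb1, a beta-defensin (1.52 ± 0.19), Socs2, an inhibitor of growth hormone signalling (1.29 ± 0.18), Spata24 (1.21 ± 0.12) and Pnldc1 (1.24 ± 0.21). Acmsd fell from 10.6 ± 4.22 to 2.51 ± 0.359 FPKM (-1.65 ± 0.26), Cbs, cystathionine beta-synthase, fell by 1.22 (SE 0.20), Slc25a15, the mitochondrial ornithine carrier, by 1.16 (SE 0.18) and Tars1, a threonyl-tRNA synthetase, by 0.90 (SE 0.12). Ptgds (-1.70 ± 0.27), Insc (-1.32 ± 0.20), Sdc1, a cell surface proteoglycan (-1.12 ± 0.15), St3gal1 (-1.08 ± 0.18), Ncald (-0.97 ± 0.13) and Rnd1 (-0.92 ± 0.12) fell too. limma called 32 genes, 18 higher and 14 lower, 21 of them changed at least 2-fold, with 1265 unadjusted; adjusted p of the genes named ran from 0.0083 to 0.0448. Without the divergent libraries 303 genes were called, all 32 among them. The count was 199 without control 1, 0 without control 2, 4 without control 3, and 2, 1 and 1 without combined 1, 2 and 3, the block moved it to 3, no filter to 10 and only the groups compared to 0.

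**Figure D1:**
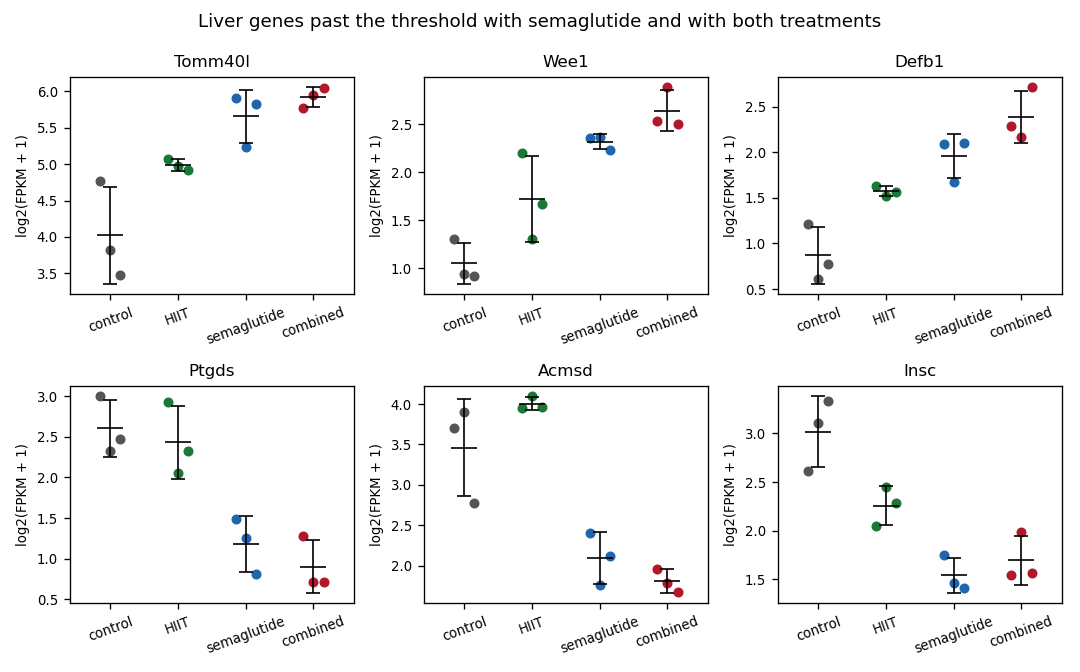
Levels of Tomm40l, Wee1, Defb1, Ptgds, Acmsd and Insc in the 12 liver libraries as log2(FPKM + 1), 1 point per library, with group mean and SD (n = 3). Acmsd averaged 10.6 FPKM in controls, 15.1 with HIIT, 3.34 with semaglutide and 2.51 with both.

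In the combined livers camera called 13 lists, 8 higher and 5 lower. Clock genes were called higher at adjusted p = 0.000282, with 11 of 16 above control (median 0.54), and 14 of the 16 passed when adjusted over the list alone, 11 higher, such as Tef (0.91 ± 0.17), and 3 lower. FAO genes (27 of 27, median 0.45, with Fgf21 at 1.58 ± 0.32, Ppara at 0.98 ± 0.21 and Acot1 at 1.84 ± 0.39) were called higher at adjusted p = 6.25e-07. So were lipid droplet genes (15 of 17, median 0.55, with Cidec at 2.7 ± 0.77 and G0s2 at 1.68 ± 0.37) at adjusted p = 0.00314, and endothelial markers (11 of 12, median 0.4, with Plvap at 0.76 ± 0.21) at adjusted p = 0.00553. Acute phase genes were called lower, 19 of 19 with a median of -1.43 and Fgg at -1.52 ± 0.45, at adjusted p = 2.18e-13; the median was -2.22 without control 1 and -0.85 without control 3. For each of these 5 lists adjusted p = 0.566 with an estimated correlation. They held 91 members, of which 2 passed over all genes, 39 adjusted over the list alone and 45 unadjusted.

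Another 8 lists were called in the combined livers, at adjusted p 2.24e-05 to 0.0372, and adjusted p = 0.566 to 0.924 with an estimated correlation. Xenobiotic metabolism (Por, 0.62 ± 0.19), female-biased (Acot3, 3.42 ± 0.76; Abcd2, 1.41 ± 0.32), mitochondrially encoded and erythroid genes were higher, and gluconeogenesis (Tat, -1.03 ± 0.23), male-biased (Cyp2u1, -0.58 ± 0.13), complement (C3, -0.83 ± 0.25) and ER stress genes (Calr, -0.61 ± 0.22) lower. Of their 109 members 1 passed over all genes, 17 adjusted over the list alone and 36 unadjusted. Omitting control 3 ended 5 of these calls (adjusted p 0.249 to 0.401), combined 2 ended 5 (0.0578 to 0.265), leaving 8 in all, combined 1 ended 3 (0.054 to 0.116), control 1 and combined 3 ended 2 each (both 0.157, and 0.488 and 0.642) and control 2 ended 1 (0.124). Scaling ended gluconeogenesis and mitochondrial mRNAs (both adjusted p = 0.0768).

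Semaglutide alone and combined treatment shared 15 liver genes against control, 8 higher (Bnip3, Defb1, Mgll, Per2, Pex11a, Socs2, Tomm40l, Wee1) and 7 lower (Acmsd, Cbs, Insc, Ncald, Ptgds, Rnd1, Sdc1). Those outside the naming rule, such as Mgll, were chosen after their values were seen. Independent lists of these sizes would share 0.045 and 0.065. Simulated unchanged groups shared 0, which tells nothing: few genes pass there. Across genes, which are not independent replicates, the 2 sets of changes correlated at 0.672 against a simulated 0.502, with a covariance of 0.094 against 0.035. The 3 controls are too few to split, so part of the excess may come from the shared controls. The count was 118 without control 1, 0 without control 2, 3 without control 3, 7, 31 and 0 without semaglutide 1, 2 and 3, and 1, 0 and 1 without combined 1, 2 and 3. HIIT shared 0 genes with either, since limma called 0 genes for it (747 unadjusted); its changes correlated with those of semaglutide at 0.471 against a simulated 0.501 and with those of combined treatment at 0.517 against 0.499, with covariances of 0.061 and 0.057 against 0.035.

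Combined treatment against HIIT in the liver asked what semaglutide added to training. Socs2 rose (1.60 ± 0.18; limma adjusted p 0.0619 to 0.0718 without HIIT 2, HIIT 3 or combined 2), with Pex11a (1.48 ± 0.22), Lgals4, a galectin (1.38 ± 0.21), Spata24 (1.28 ± 0.12) and Gbp11 (1.11 ± 0.16). Acmsd fell from 15.1 ± 0.922 FPKM (SD, n = 3) to 2.51 ± 0.359 (-2.20 ± 0.26), and Ncald (-1.19 ± 0.13), Pdia6, a protein disulfide isomerase (-0.93 ± 0.14), Tars1 (-0.83 ± 0.12) and Trim14 (-0.82 ± 0.11) fell. limma called 12 genes, 5 higher and 7 lower, with adjusted p of those named from 0.00467 to 0.0483 and 1239 genes unadjusted. Without the divergent libraries it called 782, all 12 among them. The count was 2 without HIIT 2, 0 without HIIT 3, and 5, 2 and 3 without combined 1, 2 and 3, with the block it was 5, without a filter 7 and with only the groups compared 552.

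Against HIIT in liver camera called 10 lists, 6 higher and 4 lower, each with adjusted p = 0.861 with an estimated correlation. Lipid droplet genes (16 of 17 higher, median 0.37, with Plin4 at 2.50 ± 0.64) and FAO genes (23 of 27, median 0.19, with Cpt1a at 0.63 ± 0.18) were called higher at adjusted p = 0.00622 and 0.00601; the first median was 0.21 without HIIT 2 and 0.16 without combined 2. Male-biased genes were called lower (13 of 15, median -0.71, with Elovl3 at -1.10 ± 0.31) at adjusted p = 3.84e-05. Of their 59 members 0 passed with limma over all genes, 6 adjusted over the list alone and 16 unadjusted. Female-biased, MHC class II, clock (Per1, 0.90 ± 0.19) and immediate early genes (Myc, 1.32 ± 0.25; Jun, 1.67 ± 0.51) were called higher and fatty acid synthesis (Acly, -1.21 ± 0.31; Fasn, -1.16 ± 0.35), cholesterol synthesis and ER stress genes (Hspa5, -0.64 ± 0.19) lower, at adjusted p 0.00622 to 0.0226. Of these 108 members 0 passed with limma over all genes, 11 adjusted over the list alone and 25 unadjusted. Omitting combined 2 or combined 3 ended 3 of these 7 calls each (adjusted p 0.0816 to 0.163, 0.167 to 0.217), combined 1 and HIIT 2 ended 2 each (0.208 and 0.938, 0.0611 and 0.0782) and HIIT 1 ended 1 (0.0759). Scaling ended the clock call (adjusted p = 0.0543).

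Combined treatment against semaglutide in the liver asked what training added to the drug. No gene passed. Among genes higher with both, the smallest p were those of Gbp11 (1.31 ± 0.16, limma adjusted p = 0.0614), the MHC class I genes H2-Q5 (1.22 ± 0.18) and H2-T10 (0.79 ± 0.13) and the RNA helicase gene Mov10 (0.97 ± 0.15), with Cyp2j9 (1.25 ± 0.21). Lower were the chaperone gene Dnajb9 (-0.81 ± 0.17), Zfp428 (-0.72 ± 0.16), Nup62 (-0.63 ± 0.14), Mgat2 (-0.54 ± 0.09) and Gtf2e1 (-0.51 ± 0.10). limma called 0 genes, with 812 unadjusted; it called 1 without semaglutide 2 or semaglutide 3, 2 without combined 3, 45 without the divergent libraries, 1 after scaling, with the block or with a pseudocount of 0.1, and 7 as transcripts one by one.

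Camera called 11 lists here, 7 higher and 4 lower. Interferon genes were called higher with 21 of 23 above semaglutide (median 0.49, with Irf7 at 1.23 ± 0.34 and Stat2 at 0.35 ± 0.10), at adjusted p = 2.78e-09. Heat shock (10 of 11, median -0.61, with Hspa1b at -1.14 ± 0.28 and Bag3 at -1.08 ± 0.32), OXPHOS (29 of 30, median -0.29) and lipid droplet genes (14 of 17, median -0.49, with Plin5 at -0.71 ± 0.20) were called lower at adjusted p = 0.00027, 5.37e-05 and 0.00503. For each of the 4 lists adjusted p = 0.815 with an estimated correlation. Without semaglutide 2 the medians of heat shock, OXPHOS and lipid droplet genes were -0.25, -0.02 and 0, and without semaglutide 3 that of interferon genes was 0.3. Of the 81 members 0 passed with limma over all genes, 2 adjusted over the list alone and 16 unadjusted. Cholesterol synthesis, bile acid (Abcg5, 1.27 ± 0.25), xenobiotic (Cyp1a2, 0.64 ± 0.20), secreted protein (Apoa1, 1.40 ± 0.46), MHC class II and complement genes were called higher and ER stress genes lower, at adjusted p 0.000188 to 0.0456, and adjusted p = 0.815 to 0.867 with an estimated correlation. Of their 115 members 0 passed with limma over all genes, 5 adjusted over the list alone and 12 unadjusted. Omitting semaglutide 2 ended 5 of these 7 calls (adjusted p 0.218 to 0.589) and turned cholesterol, bile acids and secreted proteins, and semaglutide 3 ended 4 (0.0631 to 0.158), leaving 7 in all. Omitting semaglutide 1, combined 2 and combined 3 ended 2 each (0.123 and 0.388, 0.144 and 0.332, 0.0607 and 0.765, the last turning cholesterol synthesis), and combined 1 ended 1 (0.101). Scaling ended cholesterol synthesis and complement (both adjusted p = 0.053) and ER stress (0.118).

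The liver interaction asked whether the joint effect differed from the sum of the single effects. Gbp11 was the gene that passed: it averaged 3.34 ± 0.724 FPKM (SD, n = 3) in controls, 1.5 ± 0.138 with HIIT, 1.17 ± 0.0726 with semaglutide and 4.48 ± 1.14 with both (log2 interaction 2.1 ± 0.23, limma adjusted p = 0.0194). The MHC class I gene H2-T10 (1.07 ± 0.18), its regulator Nlrc5 (1.12 ± 0.21), Krt18 (1.78 ± 0.34) and Cyp2j9 (1.61 ± 0.30) had positive values. Chordc1 (-0.94 ± 0.17), Magt1 (-0.94 ± 0.21), Ern1, a sensor of ER stress (-0.82 ± 0.18), Snrnp48 (-0.75 ± 0.15) and Mgat2 (-0.59 ± 0.13) had negative ones, all 9 with adjusted p = 0.396. limma called 1 gene, with 891 unadjusted, 15 without control 1, 6 as transcripts one by one, and 0 without control 2, HIIT 1, 2 or 3, semaglutide 1 or 3 or combined 1, with the block or without a filter.

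For the liver interaction camera called 13 lists, 7 higher and 6 lower. Acute phase (18 of 19 positive, median 2.13, with Hpx at 2.54 ± 0.76), complement (14 of 14, median 0.9) and interferon genes (21 of 23, median 0.65, with Stat2 at 0.67 ± 0.15 and Zbp1 at 3.25 ± 0.82) were called positive at adjusted p = 6.6e-14, 2.88e-08 and 2.43e-12. Heat shock genes (11 of 11, median -0.7, with Hsph1 at -1.40 ± 0.37) and erythroid genes (5 of 5, median -2.07, with Hbb-bt at -2.43 ± 0.70) were called negative at adjusted p = 0.000432 and 0.000733. For these 5 lists adjusted p = 0.513 with an estimated correlation. OXPHOS (30 of 30, median -0.51) and fatty acid synthesis genes (16 of 17, median -0.71, with Acaca at -0.94 ± 0.31) were called negative at adjusted p = 1.78e-07 and 0.00112, both with adjusted p = 0.716 with an estimated correlation. Liver libraries control 3, highest in acute phase level (11.42), and semaglutide 2, highest in erythroid level (8.8), enter these values: without the first the medians of complement and fatty acid synthesis were 0.5 and -0.35, and without the second that of OXPHOS -0.27. Of the 119 members 0 passed with limma over all genes, 21 adjusted over the list alone and 45 unadjusted. Macrophage (Mpeg1, 1.66 ± 0.71), MHC class II, cell cycle and immediate early genes were also called positive and lipid droplet and FAO genes negative, at adjusted p 0.00217 to 0.0451, each with adjusted p = 0.716 with an estimated correlation. Of these 92 members 0 passed with limma over all genes or the list alone, with 8 unadjusted. Omitting control 3 ended 5 of these 6 calls (adjusted p 0.05 to 0.344), HIIT 1, semaglutide 1 and 3 and combined 1 ended 2 each (0.0755 and 0.193, 0.0772 and 0.16, 0.0537 and 0.513, 0.0863 and 0.0973), and control 1 and 2, semaglutide 2 and combined 2 and 3 ended 1 each (0.094, 0.125, 0.102, 0.0587, 0.218).

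HIIT against control in the kidney asked what training alone did there. The median change was -0.257 (log2) as deposited and -0.016 after median-ratio scaling, so changes are given scaled. Kap, the androgen-regulated kidney protein, averaged 6832 ± 2140 FPKM against 1942 ± 873 in controls (SD, n = 4; scaled log2 change 2.19), and the transporter genes Slco1a1 and Slc22a30 had 1.35 and 1.14, with Chka, choline kinase, at 0.85 and Wdr54 at 0.70. Lower were Nkain1 (-1.11), the cold-inducible Cirbp (-1.04), Fndc10 (-0.74), Herpud1, an ER stress protein (-0.72), and Tspan5 (-0.69). These 10 had the smallest p among genes whose groups did not overlap and did not pass (limma adjusted p = 0.378 each as deposited). limma called 0 of 11551 genes, with 1439 unadjusted. Without library HIIT 4 it called 2099, 50 higher and 2049 lower, but 11 after scaling.

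Camera called 3 of 39 lists with HIIT in kidney. Mitochondrial mRNAs were called higher, 13 of 13 above control with a scaled median of 0.88, among them mt-Nd4 (1.01) and mt-Nd3 (1.11), at adjusted p = 9.92e-22 and adjusted p = 0.405 with an estimated correlation. Their share of FPKM was 56.7% and 55.68% in HIIT 1 and 2, 36.47% and 29.07% in HIIT 3 and 4, 34.71 to 37.81% in control 2 to 4 and 20.53% in control 1, and the median was 0.56 without control 1 and 0.54 without HIIT 1. Androgen-responsive genes were called higher at adjusted p = 6.08e-05 (scaled median 0.47, and 0.31 without control 1; adjusted p = 0.624 with an estimated correlation, and 0.052 after scaling, which ends the call), with Kap and Slco1a1 above control and Acsm3 below it (-0.86). Of the 21 members of both lists 0 passed with limma over all genes, 3 adjusted over the list alone and 7 unadjusted. Cholesterol synthesis genes were called lower (22 of 22 as deposited, scaled median -0.22, with Insig1 at -0.39) at adjusted p = 0.0224 and adjusted p = 0.981 with an estimated correlation; 0 passed with limma over all genes, 0 adjusted over the list alone and 6 unadjusted. Omitting control 2, 3 or 4 or HIIT 1 or 2 ended that call (adjusted p 0.0578, 0.0516, 0.176, 0.081, 0.0867). Without control 1 (Lyz2, 2710 FPKM) 19 lists were called, and without control 4 there were 6.

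Semaglutide against control in the kidney asked what the drug alone did there; the median change was -0.14 (log2) as deposited and -0.01 after scaling, which is used unless stated. Grem1, a bone morphogenetic protein antagonist, fell from 3.84 ± 1.7 FPKM to 0.122 ± 0.0799 (SD, n = 4; log2 change -2.04 ± 0.29 as deposited, limma adjusted p = 0.0193). Acpp (-0.88), Mab21l3 (-0.72) and Gpr85 (-0.57) were also low but did not pass. Cyp27b1, which makes active vitamin D, averaged 61.1 ± 18.2 FPKM against 15 ± 6.18 (2.15, limma adjusted p = 0.0586 as deposited). Maob, monoamine oxidase B (1.31), Hspa8 (0.98) and the lipid droplet gene Plin5 (0.88) were higher without passing. limma called 1 gene, with 384 unadjusted; it called 2 without control 1 or semaglutide 3, 0 without control 2, control 4, semaglutide 1, semaglutide 2 or semaglutide 4, 0 after scaling, with the block, without a filter or with only the groups compared, and 5 with mitochondrial transcripts removed.

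With semaglutide in kidney camera called 18 lists, 13 higher and 5 lower. FAO genes were called higher (19 of 25 as deposited, scaled median 0.35, with the close relatives Cyp4a10 at 0.87 and Cyp4a14 at 0.95) at adjusted p = 1.1e-12, mitochondrial mRNAs (13 of 13, 0.52) at 4.74e-12 and heat shock genes (8 of 12, 0.26) at 0.000169, each with adjusted p = 0.498 with an estimated correlation. Lipid droplet genes were called higher (14 of 16, scaled median 0.28, with Plin5 and G0s2 at 0.79) at adjusted p = 3.87e-10, and adjusted p = 0.0875 with an estimated correlation; kidney library semaglutide 4 held the most Fabp4 (295 FPKM). Without control 1 the medians of FAO and mitochondrial mRNAs were 0.17 and 0.26, without semaglutide 2, 3 and 4 those of heat shock, lipid droplet and mitochondrial genes 0.15, 0.54 and 0.32. Cholesterol synthesis genes were called lower (21 of 22, scaled median -0.31, with Cyp51 at -0.62) at adjusted p = 8.4e-06, and adjusted p = 0.655 with an estimated correlation. Of these 88 members 0 passed with limma over all genes, 3 adjusted over the list alone and 17 unadjusted.

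Of the other 13 calls with semaglutide in kidney, gluconeogenesis (Pck1, 1.04), fatty acid synthesis, growth hormone axis, NRF2 target (Osgin1, 1.49), OXPHOS, clock, erythroid, thick ascending limb (TAL) and urothelium genes were higher, and macrophage, interferon, cell cycle (Mcm3, -0.77) and distal convoluted tubule (DCT) genes (Slc8a1, -0.86; Calb1, -0.85) lower. Their adjusted p ran from 1.46e-05 to 0.0488, and adjusted p = 0.498 to 0.765 with an estimated correlation; the growth hormone list was called higher although its median was -0.07 as deposited. Of their 167 members 0 passed with limma over all genes, 1 adjusted over the list alone and 12 unadjusted. Without control 1, 9 of these calls ended (adjusted p 0.0533 to 0.51) and macrophage, interferon and OXPHOS (called lower, 0.0112) genes turned. Omitting semaglutide 1, 2, 3 or 4 ended 5, 3, 4 and 3 calls (adjusted p 0.117 to 0.161, 0.141 to 0.347, 0.0587 to 0.791, 0.0715 to 0.898), control 2 and control 4 ended 2 each (both 0.0582, and 0.0904 and 0.362) and control 3 ended 1 (0.179). Scaling ended fatty acid synthesis (adjusted p = 0.157), growth hormone axis and clock (both 0.0572) and urothelium (0.26).

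Combined treatment against control in the kidney asked what training and drug did together there. No gene passed. Among genes higher with both at the smallest p, Slc22a7, an organic anion transporter, averaged 6.90 ± 5.62 FPKM against 0.577 ± 0.357 in controls (SD, n = 4; log2 change 2.14 ± 0.39), Slc22a19 had 1.92 ± 0.39, Akr1c14 1.37 ± 0.28 and Nat8f7 1.12 ± 0.23. Cyp24a1, which degrades vitamin D, averaged 8.28 ± 4.13 FPKM against 78.4 ± 32.9 (-3.10 ± 0.62), and Plk3 (-1.33 ± 0.27), Slc16a1, a monocarboxylate transporter (-1.35 ± 0.33), Mab21l3 (-0.83 ± 0.21) and Gpr85 (-0.70 ± 0.16) were also lower. Their limma adjusted p ran from 0.256 to 0.654. limma called 0 genes, with 345 unadjusted, 1 after scaling and 2 with mitochondrial transcripts removed.

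Camera called 19 lists in the combined kidneys, 11 higher and 8 lower. DCT markers were called lower (7 of 7, median -0.73, with Slc8a1 at -1.08 ± 0.29 and Slc12a3 at -0.73 ± 0.34) at adjusted p = 4.7e-06, and phosphate and vitamin D genes (9 of 10, median -0.48, with Cyp24a1, Vdr at -0.87 ± 0.29 and Calb1 at -1.37 ± 0.45, a member of both lists) at 0.000208. Erythroid genes were called higher (6 of 6, median 0.69, and 1.2 without combined 4) at 1.14e-06. For these 3 lists adjusted p = 0.492 with an estimated correlation. Cholesterol synthesis genes were called lower (20 of 22, median -0.44, with Insig1 at -0.73 ± 0.22 and Msmo1 at -0.89 ± 0.28) at adjusted p = 1.32e-07 and adjusted p = 0.564 with an estimated correlation. Clock genes were called higher (11 of 18, median 0.2, and 0.09 without control 3, with Dbp at 1.27 ± 0.36 and Per3 at 0.71 ± 0.19 above control and Npas2 at -0.76 ± 0.21 below it) at adjusted p = 0.00207 and adjusted p = 0.561 with an estimated correlation. Of these 63 members 0 passed with limma over all genes, 12 adjusted over the list alone and 28 unadjusted.

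The other 14 calls in the combined kidneys had adjusted p from 1.14e-06 to 0.0464, and adjusted p = 0.492 to 0.824 with an estimated correlation. Lipid droplet, FAO, endothelial, NRF2 target, OXPHOS, mitochondrially encoded, heat shock, TAL (Slc12a1, 1.14 ± 0.51) and androgen-responsive genes (Kap, 1.76 ± 0.44; Slco1a1, 1.35 ± 0.32) were higher. Macrophage, MHC class II, complement (C1qc, -1.32 ± 0.75), fibrosis (Mmp2, -1.03 ± 0.53) and cell cycle genes were lower. Of their 193 members 0 passed with limma over all genes, 4 adjusted over the list alone and 14 unadjusted. Omitting control 1 ended 12 calls (adjusted p 0.053 to 0.979), leaving 12 in all. It turned macrophage, MHC class II, complement, fibrosis, NRF2 and OXPHOS (called lower, 0.00262) genes. Omitting combined 1 ended 3 (0.0519 to 0.0689), and control 3, combined 2 and combined 3 ended 2 each (0.0722 and 0.133, 0.103 and 0.201, 0.119 and 0.185). Scaling ended lipid droplet (adjusted p = 0.108), endothelial (0.125) and OXPHOS (0.0636).

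The kidney treatments, where limma called 0, 1 and 0 genes, could share 0 (1439, 384 and 345 unadjusted). Across genes, the changes with semaglutide and with both correlated at 0.759 against a simulated 0.501, with a covariance of 0.047 against 0.032, but at 0.075 with a covariance of 0.007 once each was set against its own 2 controls. HIIT correlated with semaglutide at 0.456 against a simulated 0.502 (covariance 0.029 against 0.032) and with both at 0.561 against 0.501 (0.04 against 0.032), and with split controls at -0.108 and 0.008 (covariances -0.011 and 0).

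Combined treatment against HIIT in the kidney asked what semaglutide added to training there; the median change was 0.164 as deposited and -0.002 after scaling, which is used unless stated. Eif4ebp3 (1.39), the clock gene Cry1 (0.86) and the mitochondrial Coq10b (0.73) were higher and Cyp24a1 (-2.12), Acmsd (-1.22), Fabp7 (-0.89), Il18 (-0.77) and the clock gene Npas2 (-0.73) lower, none of which passed (limma adjusted p from 0.286 to 0.763 as deposited). limma called 1 gene, with 686 unadjusted, and 3 after scaling; it called 0 without HIIT 1, HIIT 2, combined 2 or combined 3 or with only the groups compared, 4 without HIIT 4 and 2 with mitochondrial transcripts removed.

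Against HIIT in kidney camera called 18 lists, 9 higher and 9 lower. FAO genes (24 of 25 higher as deposited, scaled median 0.26, with Cyp4a10 at 0.71) were called higher at adjusted p = 7.73e-07, and MHC class II genes lower (7 of 7, -0.75) at 9.64e-05, both with adjusted p = 0.654 with an estimated correlation. Clock genes were called higher (14 of 18, 0.36, with Per2 at 0.65 and Per3 at 0.62) at adjusted p = 1.88e-05, and 9 passed when adjusted over the list alone. Phosphate and vitamin D genes were called lower (8 of 10, -0.45) at adjusted p = 1.88e-05, and for both lists adjusted p = 0.466 with an estimated correlation. DCT markers were called lower (7 of 7, -0.67, with Trpv5 at -0.90) at 1.64e-09 (adjusted p = 0.2 with an estimated correlation). Fibrosis genes were called lower (14 of 20, -0.33) at 1.88e-05 (adjusted p = 0.717 with an estimated correlation) and complement genes lower (8 of 12, -0.35) at 0.00695 (adjusted p = 0.726 with an estimated correlation), the last call ending after scaling (adjusted p = 0.234). HIIT 4 held more Col1a1 (10.9 FPKM), C1qa (19.7) and Cd74 (200) than the other HIIT kidneys (at most 2.46, 7.94 and 123); without it the MHC class II, fibrosis and complement medians were -0.58, -0.24 and -0.2 scaled and -0.23, 0.04 and 0.1 as deposited, and camera still called all 3 lower (adjusted p 0.0043, 0.000916 and 0.0455). Of these 99 members 1 passed over all genes, 11 adjusted over the list alone and 22 unadjusted. Gluconeogenesis (Pck1, 0.82), glycolysis, heat shock (Hspa1b, 1.73, a near-identical copy of Hspa1a), erythroid, TAL, collecting duct (Aqp2, 0.88; Aqp4, 1.28) and urothelium genes were also called higher. Cholesterol synthesis, whose median was 0.01 as deposited, interferon, cell cycle and mitochondrially encoded genes were called lower. These 11 calls had adjusted p 2.3e-07 to 0.0391, and adjusted p = 0.654 to 0.826 with an estimated correlation. Of these 139 members 0 passed with limma over all genes, 3 adjusted over the list alone and 21 unadjusted. Omitting HIIT 4 ended 9 of these 11 calls (adjusted p 0.0646 to 0.783), leaving 10 in all, HIIT 3 ended 4 (0.0849 to 0.133), combined 1 and combined 3 ended 3 each (0.0503 to 0.121, 0.0716 to 0.171). HIIT 1 and HIIT 2 ended 2 each (0.0902 and 0.0972, 0.0559 and 0.0921) and combined 4 ended 1 (0.212), while scaling ended interferon (0.205) and collecting duct (0.0537).

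Combined treatment against semaglutide in the kidney asked what training added to the drug there. Grem1 (1.10 ± 0.29), Slc22a19 (1.53 ± 0.39), Slco1a1 (1.44 ± 0.32) and Akr1c14 (1.18 ± 0.28) were higher without passing. Cyp27b1 (-1.01 ± 0.33), the mitochondrial carrier gene Slc25a25 (-1.01 ± 0.28), Plk3 (-0.86 ± 0.27), Bex1 (-0.80 ± 0.20) and Tsc22d1 (-0.59 ± 0.21) were lower without passing (limma adjusted p = 1 for each). limma called 1 gene, with 132 unadjusted, and 0 without semaglutide 2, 3 or 4 or without any of the 4 combined libraries, after scaling, with the block, without a filter, with a pseudocount of 0.1, with only the groups compared or with mitochondrial transcripts removed.

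Androgen-responsive genes were called higher against semaglutide in kidney (7 of 8, median 0.4, and 0.25 and 0.23 without semaglutide 4 and combined 3, with Kap at 1.01 ± 0.44), at camera adjusted p = 0.000109 and adjusted p = 0.422 with an estimated correlation. Of the 8 members 0 passed with limma over all genes, 1 adjusted over the list alone and 2 unadjusted. It was the 1 of 15 calls that no single library ended. Endothelial (Egfl7, 0.40 ± 0.17), collecting duct (Aqp2, 1.13 ± 0.44) and podocyte genes were also called higher. Lower were fatty acid synthesis, lipid droplet (G0s2, -0.55 ± 0.21), FAO, MHC class II, fibrosis, ER stress, NRF2 target, adipocyte, DCT, tubular injury and vitamin D genes. These 14 calls had adjusted p 1.12e-06 to 0.0486, and adjusted p = 0.284 to 0.799 with an estimated correlation. The NRF2 list was called lower with a median of 0.04. Of the 182 members of these 14 lists 0 passed with limma over all genes, 0 adjusted over the list alone and 8 unadjusted. Omitting semaglutide 4 (Adipoq, 37.2 FPKM) ended 7 calls (adjusted p 0.0552 to 0.924), leaving 9 in all, and turned the adipocyte list. Omitting semaglutide 1, 2 or 3 ended 1, 3 and 6 calls (adjusted p 0.359, 0.0573 to 0.665, 0.106 to 0.445) and combined 1, 2, 3 or 4 ended 2, 5, 2 and 4 (0.0603 and 0.0712, 0.0524 to 0.251, 0.0528 and 0.113, 0.059 to 0.0814). Scaling left 8 calls, ending fatty acid synthesis, MHC class II, fibrosis, NRF2, DCT, podocyte and tubular injury (adjusted p 0.0507 to 0.259).

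The kidney interaction asked whether the joint effect differed from the sum there; the median was 0.311 as deposited and 0.017 after scaling, which is used. Grem1 (1.81), Tspan5 (0.97), Niban1 (0.89) and Acpp (0.73) had positive values. Negative values were led by Rdh9 (-1.28), G0s2 (-1.25), Tra2a (-1.16), Ier5l (-1.15) and Lekr1 (-0.78). None passed (limma adjusted p from 0.587 to 0.629 as deposited): limma called 0 genes, with 456 unadjusted, and 1 without control 1.

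For the kidney interaction camera called 7 lists, 1 higher and 6 lower. Mitochondrial mRNAs were called negative (13 of 13, scaled median -0.96, with mt-Nd4 at -1.18) at adjusted p = 1.52e-25 and adjusted p = 0.251 with an estimated correlation (56.7% and 55.68% of FPKM in HIIT 1 and HIIT 2), while with limma 0 of the 13 passed over all genes, 0 adjusted over the list alone and 0 unadjusted. Collecting duct markers were called positive (9 of 9, scaled median 0.42, with Aqp2 at 1.59 and Aqp3 at 1.15), and lipid droplet (-0.22), fibrosis (-0.11), NRF2 (-0.21), DCT (-0.23) and vitamin D genes (-0.21) negative by scaled medians, all 5 with positive medians as deposited. The 6 lists had adjusted p 0.00193 to 0.0268, and adjusted p = 0.839 to 0.948 with an estimated correlation. Of their 76 members 0 passed with limma over all genes, 2 adjusted over the list alone and 5 unadjusted. Each of the 6 calls ended without some libraries: control 1, 2, 3 or 4 ended 3, 2, 2 and 1 (adjusted p 0.265 to 0.701, 0.105 and 0.215, 0.232 and 0.749, 0.432), HIIT 1, 2, 3 or 4 ended 1, 1, 2 and 4 (0.0861, 0.146, 0.0972 and 0.116, 0.0543 to 0.176). Omitting semaglutide 1, 2, 3 or 4 ended 2, 1, 4 and 3 (both 0.0898, 0.147, 0.159 to 0.448, 0.0683 to 0.599) and combined 1, 3 or 4 ended 1, 2 and 1 (0.0555, 0.0647 and 0.0699, 0.0548). The lists called numbered 17 without control 1, 11 without HIIT 1 or semaglutide 2 and 4 without semaglutide 3, and scaling left 3, ending lipid droplet (0.122), fibrosis (0.788), DCT and vitamin D (both 0.216).

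Whether a treatment acted differently in the 2 tissues was tested on the 9505 genes measured in both. The HIIT effect differed for Herpud1, 0.58 in liver and -1.01 in kidney (difference 1.59 ± 0.269, adjusted p = 0.0243), and Cdc42ep4, 0.49 and -0.62 (1.11 ± 0.205, adjusted p = 0.0471), 2 genes in all with 1330 unadjusted. Neither passed after scaling (differences 1.23 and 0.79, adjusted p = 0.187 and 0.12). The combined effect differed for 3 genes, Slc22a7, -1.32 in liver and 2.14 in kidney (-3.46 ± 0.515, adjusted p = 0.00283), Tomm40l, 1.90 and -0.07, the latter 0.01 after scaling (1.97 ± 0.34, adjusted p = 0.0369), and Pex11a, 1.47 and -0.20 (1.67 ± 0.304, adjusted p = 0.0369), of which Slc22a7 passed after scaling (adjusted p = 0.00695) and the others did not (0.0921 and 0.0958). Single kidney libraries stood far from their group for Cdc42ep4 (control 1, 11.1 FPKM), Pex11a (control 4, 28.9 FPKM) and Slc22a7 (combined 3, 15.3 FPKM). The semaglutide effect differed for 0 genes by this test from the limma fits, with 816 unadjusted; Nr0b2 came closest, -1.17 in liver and 0.57 in kidney (-1.73 ± 0.307, adjusted p = 0.0571, and 0.0337 after scaling, when 5 genes passed). No gene passed in the same direction in both tissues, as kidney counts of 0 (HIIT), 1 (semaglutide) and 0 (both) nearly fixed in advance. The HIIT count was 41 without liver control 1 and 1250 without kidney HIIT 4, and 0 or 1 without any other. The semaglutide count was 30 without liver control 1, 2 without kidney semaglutide 4, and 1 without liver semaglutide 1 or 2 or kidney control 3. The combined count was 21 without liver control 1, 5 without kidney control 1, and 1 without liver control 2, any liver combined library, or kidney control 2 or 4 or combined 1 or 4.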

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

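The tests that weigh the 3 patterns below were chosen after their results had been seen.

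Liver library semaglutide 2 held transcripts of striated muscle, fat and plasma cells. An effect of semaglutide on them is argued against, since the other semaglutide libraries differed from the other groups by a median of -0.05 (log2) over the 9 skeletal muscle markers. RNA of another tissue in that library may account for them: 9 of 9 muscle markers stood above every other liver library, with a median excess of 9.25, as did 6 of 8 adipocyte and 8 of 8 B and plasma cell markers, but 3 of 10 pancreatic acinar markers. Acta1 was at 3900 FPKM and Adipoq at 137 FPKM. How it came there stays open.

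In kidney with HIIT 85.2% of genes were lower on the deposited scale, with a median of -0.257. A larger mitochondrial share may account for the fall. Removing those transcripts and rescaling moved the median to -0.065, but rescaling alone shrinks any common shift. An effect of HIIT on most mRNAs cannot be told apart from that share, as FPKM are shares of a total. Without HIIT 4, 12 genes passed after that removal and 2099 before it.

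Acute phase genes were lower in every treated liver group. Control 3 alone is argued against as the source, since without it the list's median was still -0.85 or lower in each treatment. An effect of the treatments cannot be told apart from differences among the 3 controls: control 1 lay 0.06 (log2) above the treated mean, control 2 1.9 and control 3 2.98. In control 1, 1 of 19 members stood above every treated library, and in each of the others 18. Removing control 1, nearest the treated livers, had to widen the gap. By fry the list then passed with HIIT, semaglutide and both (adjusted p = 0.000948, 0.00173 and 0.0028). It failed with all libraries (0.0859 to 0.37) and without control 2 or 3 (0.226 to 0.64).

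Effects differed between the tissues by a test of the difference for HIIT on Herpud1 (1.59) and Cdc42ep4 (1.11) and for combined treatment on Slc22a7 (-3.46), Pex11a (1.67) and Tomm40l (1.97), as liver minus kidney log2 change. After median-ratio scaling Slc22a7 alone of these 5 passed (adjusted p = 0.00695, and 0.0921 to 0.187 for the others). In liver the effect of semaglutide with HIIT less that without it differed for Gbp11 (2.1). Among loci without a gene name, outside the main measurement, limma called 1 of 443 for combined treatment against HIIT in kidney, with 42 at an unadjusted p under 0.05.

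Single kidney libraries stood far from the other 3 of their group, by a test of the gap against the range that chance passes in about 1 in 20 groups. Of 24 tests of library measures 3 passed, all in control 1: 12461 genes at 1 FPKM or more, 11.53% of FPKM at loci without a name and a median correlation of 0.91. Of 304 tests of named genes 27 passed. In control 1 these were C1qc (170 FPKM), Cdc42ep4 (11.1), Cirbp (60.3), Cry1 (2.63), Il18 (4.41), Lyz2 (2710), Mcm3 (7.7), Mmp2 (26.4), Trpv5 (8.83) and Tsc22d1 (160). In control 2 they were Insr (7.46 FPKM) and Nkain1 (1.21), and in control 4 Pex11a (28.9). In HIIT 4 they were Adipoq (0.572 FPKM), Mcm3 (5.2), Niban1 (4.64), Slc12a1 (152) and Trpv5 (17.1), and in HIIT 1 Nkain1, listed at 0. In semaglutide 4 Adipoq was at 37.2 FPKM, in semaglutide 3 Hspa8 at 865 and Nkain1 at 5.6, and in semaglutide 1 Niban1 at 2.56 and Tra2a at 8.95. In combined 2 Calb1 was at 83.2 FPKM and Kap at 2710, and in combined 3 Slc22a7 at 15.3.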

How the results depend on the processing

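The alternatives with divergent libraries left out, with mitochondrial transcripts removed, and with single libraries left out for lists and overlaps were chosen after the data had been seen. Of the 69 calls of genes named in the text, 66 stayed past the threshold with a pseudocount of 0.1, 49 after median-ratio scaling, 25 without a filter and 16 with the replicate block, and 0 of them changed sign under these or without single libraries. Of the calls that each library enters, in either tissue, 54, 0 and 12 of 59 stayed without control 1, 2 and 3, 20, 24 and 1 of 37 without semaglutide 1, 2 and 3, 6, 4 and 5 of 33 without combined 1, 2 and 3, and 6, 2 and 0 of 11 without HIIT 1, 2 and 3, while 52 of 68 liver calls stayed without the divergent libraries. Among named values that had not passed, 3 changed sign, under 7 settings in all: Insr in liver HIIT against control was 0.03, 0.01 and 0.03 without control 1, control 2 and HIIT 2 (-0.09 to 0.03 over single libraries), Tomm40l in kidney combined against control was 0.01 after scaling and 0.03 and 0.02 without control 2 and combined 4 (-0.14 to 0.03), and Adipoq in kidney combined against semaglutide was 0.22 without semaglutide 4 (-1.53 to 0.22). Where values differ below, the cause was not tested. Depth is unknown and its limit could not be set.

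Counts of genes past the threshold in liver, in the order HIIT, semaglutide and combined against control, combined against HIIT, combined against semaglutide and interaction, were 0, 74, 32, 12, 0 and 1. Without the filter, which adds weakly expressed genes to the tests, semaglutide and combined treatment against control and combined against HIIT had 23, 10 and 7 and the interaction 0. With only the groups compared in the fit the same 3 were 0, 0 and 552. Tested as transcripts one by one, HIIT had 6, semaglutide 7, combined against semaglutide 7 and the interaction 6. A pseudocount of 0.1 or scaling gave 1 for combined against semaglutide. Without the divergent libraries combined treatment had 303 against control, 782 against HIIT and 45 against semaglutide. Leaving out single libraries gave 0 to 106, 0 to 252, 0 to 199, 0 to 12, 0 to 2 and 0 to 15 in that order, and 0 to 118 for the 15 genes shared by semaglutide and combined treatment.

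In kidney the counts were 0, 1, 0, 1, 1 and 0 in the same order. Semaglutide against control and combined against semaglutide fell to 0 without the filter, after scaling and with only the groups compared, as did combined against HIIT with only the groups compared, and combined against semaglutide with a pseudocount of 0.1. Scaling gave 1 for combined against control and 3 against HIIT. Removing mitochondrial transcripts gave 5 for semaglutide, 2 for combined against control, 2 against HIIT and 0 against semaglutide. Without control 1, semaglutide had 2 and the interaction 1. Leaving out single libraries gave 0 to 2099 for HIIT, 0 to 2 for semaglutide, 0 to 4 for combined against HIIT, 0 to 1 for combined against semaglutide and 0 to 1 for the interaction. Between tissues the counts were 2, 0 and 3 for HIIT, semaglutide and combined treatment, 0, 5 and 1 after scaling, and 0, 2 and 7 without the divergent libraries. The last was 1 without the filter and 6 with a pseudocount of 0.1. Leaving out single libraries gave 0 to 1250, 0 to 30 and 1 to 21.

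Of same-numbered pairs, 2 of 18 in liver and 9 of 24 in kidney correlated above 0.1. Medians were -0.085 and 0.079 (other pairs 0.028 and -0.017). Pairing is open, with 0 and 2 libraries closest to their own number. With the replicate block the liver counts were 10 for semaglutide, 3 for combined treatment, 5 and 1 for combined treatment against HIIT and against semaglutide, and 0 for the interaction, and in kidney 0 for semaglutide and for combined against semaglutide. At an unadjusted p under 0.05 with at least a 2-fold change, liver had 85, 184, 147, 103, 47 and 164 genes and kidney 63, 25, 56, 75, 21 and 67.

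Lists called numbered 15, 15, 13, 10, 11 and 13 in liver and 3, 18, 19, 18, 15 and 7 in kidney, and 0 in each with an estimated correlation. Without the divergent libraries HIIT in liver had 9, combined against semaglutide in liver 17, HIIT in kidney 19, combined in kidney 12 and the kidney interaction 17. Scaling left 8 for combined against semaglutide in kidney and 3 for the kidney interaction. Leaving out single libraries gave 9 to 14 for HIIT in liver, 8 to 14 for combined and 7 to 14 for combined against semaglutide there, and in kidney 2 to 19 for HIIT, 12 to 25 for combined, 10 to 19 against HIIT, 9 to 17 against semaglutide and 4 to 17 for the interaction.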

Other observations

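The criteria for the splits below, their repeat after median-ratio scaling and fry without libraries were chosen after results had been seen, and the lists tested by fry were fixed in advance.

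By fry, which asks whether the genes of a list move one way on balance and does not compare them with others, fatty acid oxidation, lipid droplet and clock genes passed with semaglutide in liver (adjusted p = 0.0245, 0.0245 and 0.038). None passed without the divergent libraries (0.0594, 0.0594 and 0.172), and library semaglutide 2 held adipocyte transcripts (Fabp4, 1150 FPKM). Fatty acid oxidation failed without control 2, control 3, semaglutide 1 or semaglutide 3 (0.0559 to 0.0908), lipid droplet genes without control 2, control 3 or semaglutide 3 (0.0532 to 0.0571) and clock genes without any but control 1 (0.0532 to 0.146). With combined treatment clock genes passed (adjusted p = 0.0261), also without the divergent libraries (0.0151), but not without control 2 or any combined library (0.0599 to 0.126).

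Other splits of the same libraries were counted beside each result. Where the real count is 0, every split is as large by definition and the test tells nothing. In liver a comparison of 2 groups has 10 splits, too few for a share under 0.05. The real split of HIIT and control called 0 genes, the highest other 2, and all 10 splits gave as many. For semaglutide the real count was 74 and the highest other 3, for combined treatment 32 and 3, and against HIIT 12 and 0, with 1 split as large in each. Against semaglutide it was 0 and 0, and all 10 gave as many. For lists the real counts and highest others were 15 and 16, 15 and 20, 13 and 15, 10 and 14, and 11 and 17, and 2, 5, 5, 4 and 8 splits gave as many. For the liver interaction, 9 of 100 drawn splits gave as many genes (1, highest other 2) and 38 as many lists (13, highest other 21), so chance cannot be excluded.

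In kidney there were 35 splits. For genes 35 were as large with HIIT (0, highest other 4147) and with combined treatment (0, highest other 1). Chance cannot be excluded for the lists with HIIT, with 35 as large (3, highest other 29), for semaglutide, with 2 for genes (1, highest other 1) and 30 for lists (18, highest other 26), or for the lists with combined treatment, with 25 (19, highest other 26). Nor can it against HIIT, where 3 splits were as large for genes (1, highest other 2562) and 4 for lists (18, highest other 21). Against semaglutide 1 of the 35 was as large for genes (1, highest other 0), a share under 0.05, but the count of 1 was 0 after scaling, so chance is not taken as excluded, and 10 for lists (15, highest other 19). For the kidney interaction 100 of 100 drawn splits were as large for genes (0, highest other 1874) and 93 for lists (7, highest other 26). Splits that call 4147, 2562 or 1874 genes point to a structure of the samples other than the groups. After median-ratio scaling the highest others were 1577, 5 and 83, so a shift of most genes together may carry part of it, and for HIIT a large count stayed. Between tissues 3 of 100 drawn splits were as large for HIIT (2, highest other 1129), a share under 0.05, but after scaling they were 0 and 659, so chance is not taken as excluded. There were 100 for semaglutide (0, highest other 38) and 11 for combined treatment (3, highest other 13).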
